A study of Drosophila melanogaster with 9 samples.

How the data were processed

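RNA was measured in brains of adult female *Drosophila melanogaster* aged 4 to 6 days. Each of the 9 libraries was made from a pool of 20 dissected brains. The labels give 3 groups of 3 libraries, which were unexposed wild-type flies, wild-type flies exposed orally to the bacterium Ecc15 (*Erwinia carotovora carotovora* 15, a Gram-negative bacterium fed to flies) and PGRP-LB mutant flies exposed in the same way. Per the labels' protocols, exposure lasted 16 h, whereas the series' design text speaks of a 24-hour diet given to both genotypes. No unexposed mutant library is among the samples used here. The deposited columns name the mutant PGRP-LBD, with no meaning given for the last letter. Per the labels' protocols, 250 ng of total RNA went into stranded, poly(A)-selected libraries, and all samples were sequenced in 1 lane with reads of 100 bases from both ends. Each pool holds different flies, so the spread between libraries covers flies, dissection and library preparation together.

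The deposited files are 12 tables made from the sheets of 4 workbooks, an up and a down workbook for each exposed group against the unexposed wild type. Of the 3 sheets of each workbook 2 held the full table of 17562 gene IDs for that group, identical in the up and the down workbook. The remaining sheet held the part of it with a fold of at least 1.5 (up) or at most 0.75 (down). The full table of each group was used. Per the submitters' processing notes, HISAT2, HTSeq, featureCounts and DESeq2 were used by the authors, with no role given for each; the genome build, annotation and strand setting are not given in the sources used here. The deposited values per library are whole numbers and carry the name raw data in a sheet title, yet the same control libraries differed between the 2 tables by one constant factor each. The ratio of the control values in the wild-type table to those in the PGRP-LB table had a median of 1.013, 1.017 and 1.021 in libraries S1, S2 and S3. These values are therefore treated as normalized counts that the authors scaled within each table and rounded, a score rather than raw counts. The authors' fold change and its log2 value, and the p-value and adjusted p-value, stand in further deposited columns, per the file headers, and were used only where the authors' deposited table is named.

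The pattern of missing or doubly filled whole numbers at low values gave an estimate of each library's scaling factor, between 0.732 and 1.14. In a test on simulated data with 10 known factors the largest error was 1.18%. The normalized totals were 25.3 to 27.8 M (M, mega) per library and table, and the estimated counted reads were 19.4 to 30.7 M. Columns are marked S1 to S3 within a group, and these marks could not be matched to the replicate numbers in the sample titles, so libraries are named by group and column mark. Of the gene IDs, 16839 matched a gene symbol of the BDGP6 annotation, and 4 had been turned into dates by spreadsheet software. Locations are from the BDGP6 annotation by symbol.

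The tests had been planned for raw counts. With normalized values, the planned fallback was used, which was limma-trend (limma 3.58.1, R 4.3.3) on log2(value + 1) for genes with a mean of at least 1, within each table, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. No count model was run. A total of 22 gene lists (immune pathways, stress, metabolism, neural signalling and markers of cell types that dissected brains could carry) was fixed before the data were examined. Lists with 5 or more measured members were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and limma's fry as alternatives, adjusted over all lists. With 3 libraries against 3, an exact permutation test cannot go below 0.1.

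Genes named in the text were chosen by a rule set beforehand. Part (a) took up to 10 higher and 10 lower genes per comparison with the largest log2 change among those past the threshold, with groups that did not overlap and a mean of at least 5 in the higher group. Part (b) took up to 4 members per list with the smallest adjusted p, and part (c) took PGRP-LB, DptA, AttA, AttD, pirk, Tdc2, Tbh and Oamb. A few other genes are marked as chosen after their values were seen.

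No table holds both exposed groups, and the tables were scaled separately. The report therefore sets the exposed groups side by side against the same controls without a test. For the closing section, all 9 libraries were put on one scale with median-of-ratios factors (0.985 to 1.01) and fitted together with limma. This joint fit was chosen after seeing the data.

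The fits were tested on simulated libraries with the means and scaling of the real ones and 200 genes changed by known folds. Each gene was given the median spread of genes of similar level, and genes were drawn independently. Spread particular to a gene or shared between genes was thus left out, and recovery in the real data may be lower. For the wild-type comparison (12943 genes), 57.1% of the tested genes changed by 1.5-fold, 69.6% of those changed 2-fold and 86.0% of those changed 4-fold were recovered, and 3.57% of the calls were false. For the PGRP-LB comparison (12946 genes) the shares were 63.3%, 70.0% and 80.0%, with 4.71% false. For the joint fit (13008 genes) they were 49.0%, 68.8% and 89.4%, with 2.99% false. Alternatives were quantile normalization, no filter, a filter of 1 per M normalized counts in 3 libraries, pseudocounts of 0.5 and 5, an added fold threshold of 1.5 or 0.75, each library left out, and, chosen after seeing the data, the joint fit, the photoreceptor gene ninaE as a covariate, and doubted libraries left out together. Overlap between the comparisons was set against 100 simulations of unchanged groups sharing the controls. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the tables and drew the figures.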

Results

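Gene expression was measured by poly(A) RNA sequencing in dissected brains of adult female flies in 3 groups of 3 libraries. The groups were unexposed wild type (WT control), wild type after oral exposure to the bacterium Ecc15 (WT Ecc15) and PGRP-LB mutants after the same exposure (PGRP-LB Ecc15). PGRP-LB is an amidase that degrades peptidoglycan, the bacterial cell wall polymer that activates the Imd immune pathway of flies. The series asks how peptidoglycan that reaches the brain changes gene expression there. Each library rested on an estimated 19.4 to 30.7 M counted reads (M, mega), the fewest in WT Ecc15 library S2. All values are the authors' normalized counts, scaled separately in each of 2 tables, and levels across the tables are set side by side only.

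The targeted gene was examined first. PGRP-LB (chromosome 3R, 11452849 to 11460552, minus strand, BDGP6) had values of 164, 120 and 151 in the WT control libraries and 687, 1359 and 721 in the PGRP-LB Ecc15 libraries of the same table. In the other table it stood at 167, 122 and 154 in WT control and 335, 261 and 224 in WT Ecc15. The libraries labelled PGRP-LB mutant thus held more PGRP-LB RNA than the controls, 6.06-fold (SE of the log2 change 0.27, limma adjusted p = 0.00134). The wild-type difference was not called by limma (log2 change 0.88, SE 0.19, adjusted p = 0.307), while the authors' deposited table has adjusted p = 0.0134. An exact two-sided permutation test gave p = 0.1 in both tables, the smallest value 3 libraries against 3 allow. The deposited columns name the mutant PGRP-LBD, and the labels give neither the meaning of the added letter nor the part of the gene that is changed, so a total over the whole gene does not check the label. A gene on the opposite strand, CG17230, overlaps PGRP-LB, and the strand setting of the counting is not given.

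The first comparison asked what oral exposure does to the wild-type brain. Several genes for antimicrobial peptides, short secreted proteins that kill bacteria, were higher in WT Ecc15 than in WT control brains. Diptericin B (DptB) rose 65.5-fold, from 90.7 ± 45.5 (SD, n = 3) to 6392 ± 3637 (SD, n = 3) normalized counts. Diptericin A (DptA) rose from 31.0 ± 7.81 to 2150 ± 1163 normalized counts, a log2 change of 5.91 (SE 0.45). Metchnikowin (Mtk), Drosocin (Dro) and the cecropins CecA1, CecC and CecB rose between 26.6-fold and 45.7-fold, with CecB at a log2 change of 4.73 (5.32 without WT Ecc15 S3). The peptidoglycan recognition genes PGRP-SB1, which encodes a secreted amidase, and PGRP-LF, an inhibitor of the Imd pathway, rose 18.1-fold and 4.82-fold. Rel, which encodes the NF-κB factor of the Imd pathway, rose 1.66-fold, and every exposed library lay above every control library.

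In total 16 genes were higher in WT Ecc15 and 0 were lower among 13085 genes tested (limma, adjusted p under 0.05). At an unadjusted p under 0.05, 621 genes were higher and 332 lower. The authors' deposited table gives 125 higher and 17 lower genes at an adjusted p under 0.05, and all 16 are among them. The groups did not overlap in 12.6% of the genes tested, where chance gives 10%. The other genes called were CG45045 (log2 change 4.53, SE 0.45), CG42807 (3.51, SE 0.36) and Tep1, a complement-like protein (2.45, SE 0.29). The last 3, which fall outside the naming rule and were chosen after their values were seen, were betaTub60D (5.29-fold), yellow-f (3.84-fold) and CG42711 (3.42-fold).

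**Figure D1:**
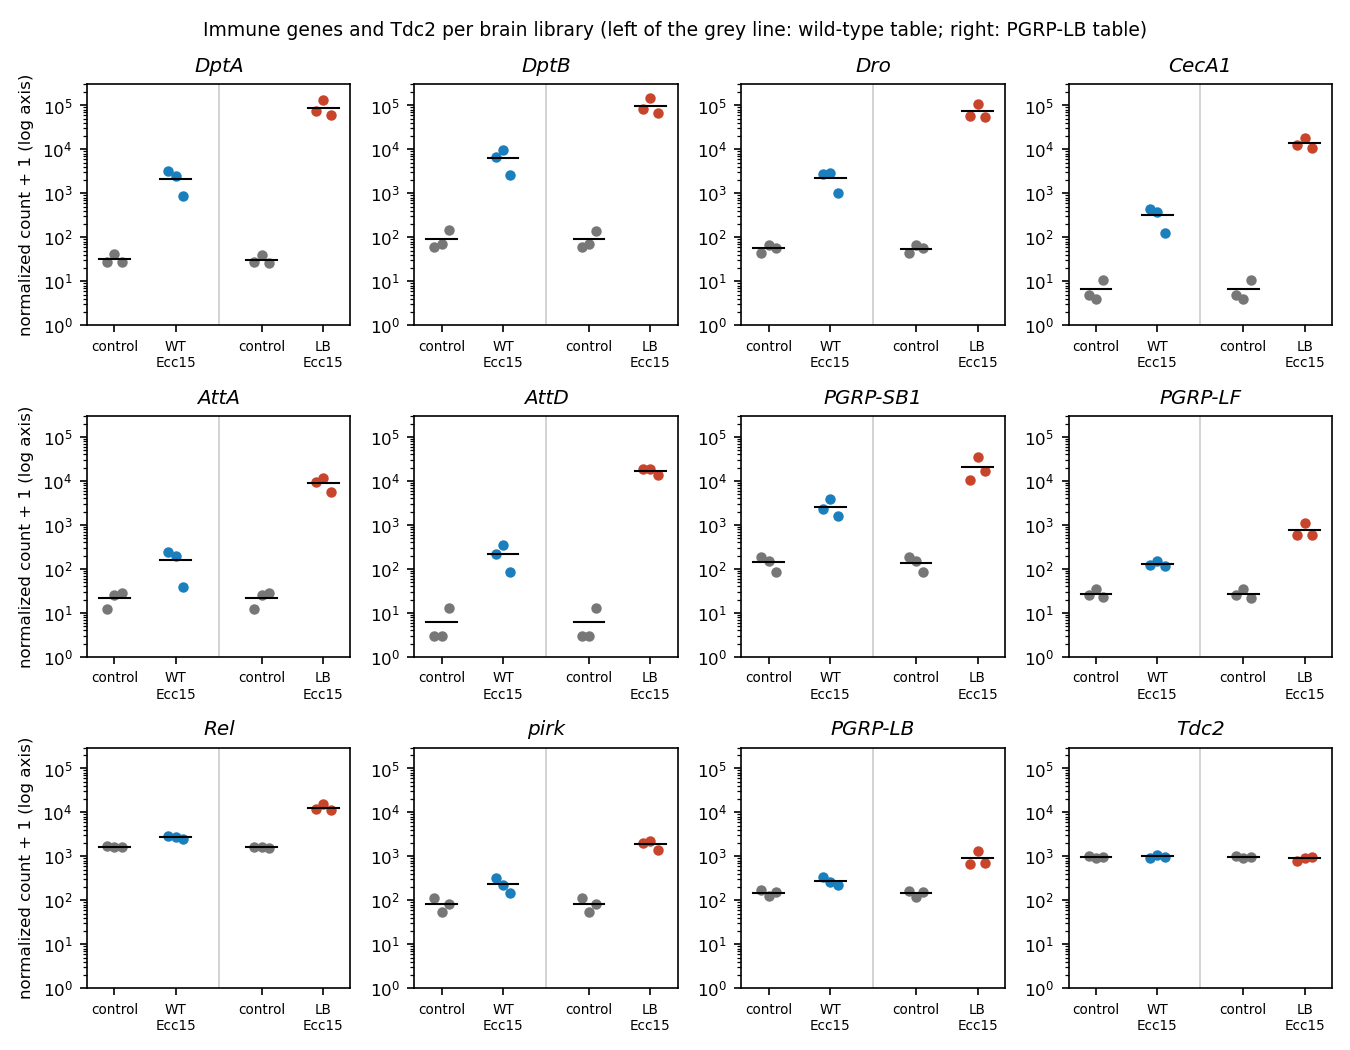
Normalized count plus 1 on a log axis for 11 immune genes and Tdc2 in each brain library, with unexposed wild-type controls in grey, WT Ecc15 in blue and PGRP-LB Ecc15 in red; each point is a library, horizontal lines are means, and the grey vertical line parts the 2 separately scaled tables. DptA lay at 25 to 40 in the controls of both tables, at 874 to 3150 in WT Ecc15 and at 59179 to 134159 in PGRP-LB Ecc15, whereas Tdc2 means lay between 899 and 1002 in every group.

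Among the 15 measured antimicrobial peptide genes limma called 7 higher (15 adjusted over the list alone), with a median log2 change of 5.08. The list was called with camera (adjusted p = 3.98e-35), and the call was lost with adjusted p = 0.161 with an estimated correlation. With fry it kept its call (adjusted p = 0.0262), as did the peptidoglycan recognition list (0.0398). Attacin D stood at 219 ± 137 against 5.33 ± 5.77 normalized counts (limma adjusted p = 0.0683), and Attacin A at 161 ± 110 against 21.3 ± 9.07 (limma adjusted p = 0.494). The authors' deposited table has adjusted p = 3.67e-05 and 0.000717 for these 2. WT Ecc15 library S3 held the lowest values of its group for DptA, DptB, Dro, AttA and AttD. Of 12 peptidoglycan recognition genes limma called 2 higher (6 adjusted over the list alone; camera adjusted p = 4.24e-09, and adjusted p = 0.161 with an estimated correlation). Of 19 genes of Imd signalling limma called Rel (2 adjusted over the list alone), and the list was not called (adjusted p = 0.352). The inhibitor pirk stood at 232 ± 87.2 against 83.3 ± 29.5 normalized counts (limma adjusted p = 0.384, and 0.00685 in the authors' deposited table). Of 18 JAK-STAT and Turandot genes limma called Tep1 (3 adjusted over the list alone; camera adjusted p = 9.54e-05, and adjusted p = 0.301 with an estimated correlation). None of 31 Toll pathway and Bomanin genes was called by limma, over all genes or adjusted over the list alone, while the list was called (median 0.37, adjusted p = 5.03e-05, and adjusted p = 0.540 with an estimated correlation). The authors' deposited table has 14 peptide, 6 recognition, 2 Imd (Rel and pirk), 2 JAK-STAT and 0 Toll genes higher, and 0 genes of these lists lower.

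Neural genes showed no limma call in this comparison. Tdc2, the neuronal tyrosine decarboxylase that makes the precursor of octopamine, stood at 1002 ± 75.2 in WT Ecc15 and 978 ± 58.1 in WT control brains (log2 change 0.03, SE 0.08). Tbh, which makes octopamine, and its receptor Oamb had log2 changes of 0.13 (SE 0.07) and 0.10 (SE 0.06). No member of the biogenic amine list (29 genes, median 0.10), the neuropeptide list (33 genes, median 0.11) or the neuron list (15 genes, median 0.04) was called by limma, over all genes or adjusted over the list alone. Camera called these lists higher at adjusted p = 0.00499, 0.00249 and 0.0386, and none held with an estimated correlation (adjusted p = 0.540, 0.540 and 0.550). The circadian clock (14 genes, median 0.00, and -0.01 after quantile normalization), insulin and nutrient (20, median 0.11), JNK and activity (13, median 0.07), detoxification (39, median -0.04) and glia (15, median -0.01) lists had no member called by limma and no camera call. The same held for 36 odorant-binding proteins, whose median of -0.10 and mean of -0.05 differed in sign from the camera direction (adjusted p = 0.888). Heat shock genes (16, median -0.23, camera adjusted p = 0.0137), ribosomal protein genes (87, median 0.09, adjusted p = 3.20e-05) and nuclear oxidative phosphorylation genes (70, median -0.07, adjusted p = 4.43e-05) had no member called by limma. With an estimated correlation these 3 lists had adjusted p = 0.540, 0.599 and 0.548. The authors' deposited table has 1 ribosomal protein gene higher (RpL38, adjusted p = 0.0348) and 0 genes called in the other 11 lists of this paragraph.

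Markers of other tissues that dissected brains can carry were measured beside these. Haemocyte markers had a median log2 change of 0.61, with all 14 above 0 and 0 called over all genes by limma (6 adjusted over the list alone). The haemocyte gene Hml stood at 9974 ± 1905 in WT Ecc15 and 4857 ± 355 in WT control brains (limma adjusted p = 0.0542). Fat body markers had a median of 0.91 over 13 genes, with 0 called by limma (4 adjusted over the list alone), and the fat body gene Lsp2 stood at 355 ± 278 against 38.3 ± 16.6 normalized counts (limma adjusted p = 0.469). The authors' deposited table has 4 haemocyte markers higher (Hml, adjusted p = 1.06e-11, Sr-CI, eater and NimC1) and 2 fat body markers (CG10621, 5.05e-07, and Lsp2, 0.0265). Camera called both lists (adjusted p = 1.27e-09 and 1.09e-06, each with adjusted p = 0.301 with an estimated correlation). On the common scale of all 9 libraries, the mean log2(value + 1) of fat body markers was 9.995 to 10.47 in WT Ecc15 and 8.789 to 9.613 in WT control. That of haemocyte markers was 10.865 to 11.281 and 10.358 to 10.707. Whether carried-over tissue added to the higher peptide genes of WT Ecc15 was not tested. Gut enzymes (22 genes, median 0.98, adjusted p = 0.00249, and adjusted p = 0.540 with an estimated correlation) and muscle genes (19, median -0.38, adjusted p = 0.0120, and adjusted p = 0.604 with an estimated correlation) were called with no member called by limma. The photoreceptor list was not called (19 genes, median -0.35, adjusted p = 0.147). The authors' deposited table has 0 calls in these last 3 lists.

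The wild-type calls depended on single libraries. Without WT control library S1, WT Ecc15 library S1 or WT Ecc15 library S2 no gene was called higher by limma (766, 403 and 425 at an unadjusted p under 0.05), and without WT control library S2 6 were called, while the log2 change of DptA stayed between 5.54 and 6.46 over all 13 alternatives, its call lost without those 3 libraries. The list calls of Toll genes and ribosomal proteins were lost without WT control S3, of biogenic amines without WT control S1, of heat shock genes without WT control S2, of neuropeptides and gut enzymes without WT control S2 or WT Ecc15 S2, of muscle without these or WT control S1, and of neurons without WT control S1 or any WT Ecc15 library. The call of Tep1 and PGRP-LF was lost without any 1 library, and that of CecB without any but WT Ecc15 S3. Counting the other settings too, Tep1 lost its call in 10 of 13 alternatives and CecB in 7 of 12.

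The second comparison set exposed PGRP-LB mutant brains against unexposed wild-type brains, so genotype and exposure change together and cannot be told apart. All 15 antimicrobial peptide genes rose (15 adjusted over the list alone), with a median log2 change of 10.01. DptA rose from 30.0 ± 7.81 to 89068 ± 39730 normalized counts (log2 change 11.43, SE 0.31, adjusted p = 6.27e-06, n = 3 per group). The genes with the largest log2 changes were edin (12.05, SE 0.28), an infection-induced peptide gene, AttD (11.76, SE 0.55), CecA2 (11.44, SE 0.30), DptA, CecA1 (11.12, SE 0.39), Dro (10.32, SE 0.28), PGRP-SC2 (10.26, SE 0.52), DptB (10.13, SE 0.38) and CG45045 (10.07, SE 0.48). Without WT control S3 the change of AttD was 12.47, and without WT control S2 that of PGRP-SC2 was 9.66. The gene white (w, chromosome X), a pigment transporter, stood at 11962, 18926 and 11128 in the mutant libraries and at 5, 6 and 13 in the controls (10.67, SE 0.35). In WT Ecc15 it was not raised (log2 change -0.43, SE 0.49). The antimicrobial peptide genes together took 1.55% to 3.02% of all normalized counts in the mutant libraries, 0.0391% to 0.139% in WT Ecc15 and 0.00229% to 0.00438% in WT control libraries.

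In total 1292 genes were higher and 838 lower in PGRP-LB Ecc15 among 13384 genes tested (limma). Of these, 839 were more than 2-fold higher and 243 more than 2-fold lower. The authors' deposited table gives 1385 higher and 949 lower, and 1951 genes were called in both, in the same direction. The groups did not overlap in 35.7% of the genes tested, where chance gives 10%. The largest falls were in Oatp33Ea, an organic anion transporter (from 721 ± 89.2 to 5.67 ± 4.73 normalized counts), asRNA:CR44291, asRNA:CR44030, the gustatory receptor Gr59d, CG9377, the cytochrome P450 gene Cyp28a5 (from 4650 ± 571 to 152 ± 18.03), CG33483, CG34456, Elo68beta and CG13978. Both antisense RNAs overlap a gene on the other strand and are uncertain, since the strand setting of the counting is not given. Values of near-identical relatives (CecA1 and CecA2, AttA and AttB, Amy-p and Amy-d) are uncertain, as the counting could split reads between them. Mtk, edin and CG45045 overlap a gene on the same strand (Stacl, Oatp74D and CG14322), which makes their values uncertain too.

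Some genes of other immune lists rose as well. Of 13 peptidoglycan recognition genes 9 rose (10 adjusted over the list alone), with PGRP-SD, a secreted recognition protein, at 12360 ± 4400 against 211 ± 61.5 normalized counts and PGRP-SB1 at 20452 ± 12380 against 138 ± 50.7. Of 19 Imd signalling genes Rel (7.79-fold), pirk (23.6-fold) and key (1.17-fold) rose and ben fell (3 higher and 2 lower adjusted over the list alone), and the call of key was lost without any 1 library (adjusted p up to 0.165) and that of ben without WT control S2 or S3 or any PGRP-LB Ecc15 library (up to 0.162). The Imd list was not called by camera (adjusted p = 0.377), while fry called it higher (adjusted p = 0.021). Of 31 Toll and Bomanin genes 18 rose (20 adjusted over the list alone), among them the Bomanins BomBc1 (27.8-fold) and BomS1 (12.3-fold), secreted peptides of the Toll response. Of 17 JAK-STAT and Turandot genes 7 rose (7 adjusted over the list alone), among them Tep4 (24.7-fold), Tep2 (3.69-fold), vir-1 (1.76-fold) and the cytokine upd3, at 35.3 ± 11.6 against 0.333 ± 0.577. Of 13 JNK and activity genes 7 rose and egr fell (9 higher and 2 lower adjusted over the list alone), with the transcription factor Ets21C up 3.39-fold. Camera called the antimicrobial peptide, recognition, Toll, JAK-STAT and JNK lists at adjusted p = 6.12e-25, 2.21e-09, 2.21e-09, 0.000134 and 0.00335. With an estimated correlation these had adjusted p = 0.196, 0.196, 0.598, 0.367 and 0.196. With fry they had adjusted p = 0.000154, 0.00066, 0.025, 0.00974 and 0.00428.

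**Figure D2:**
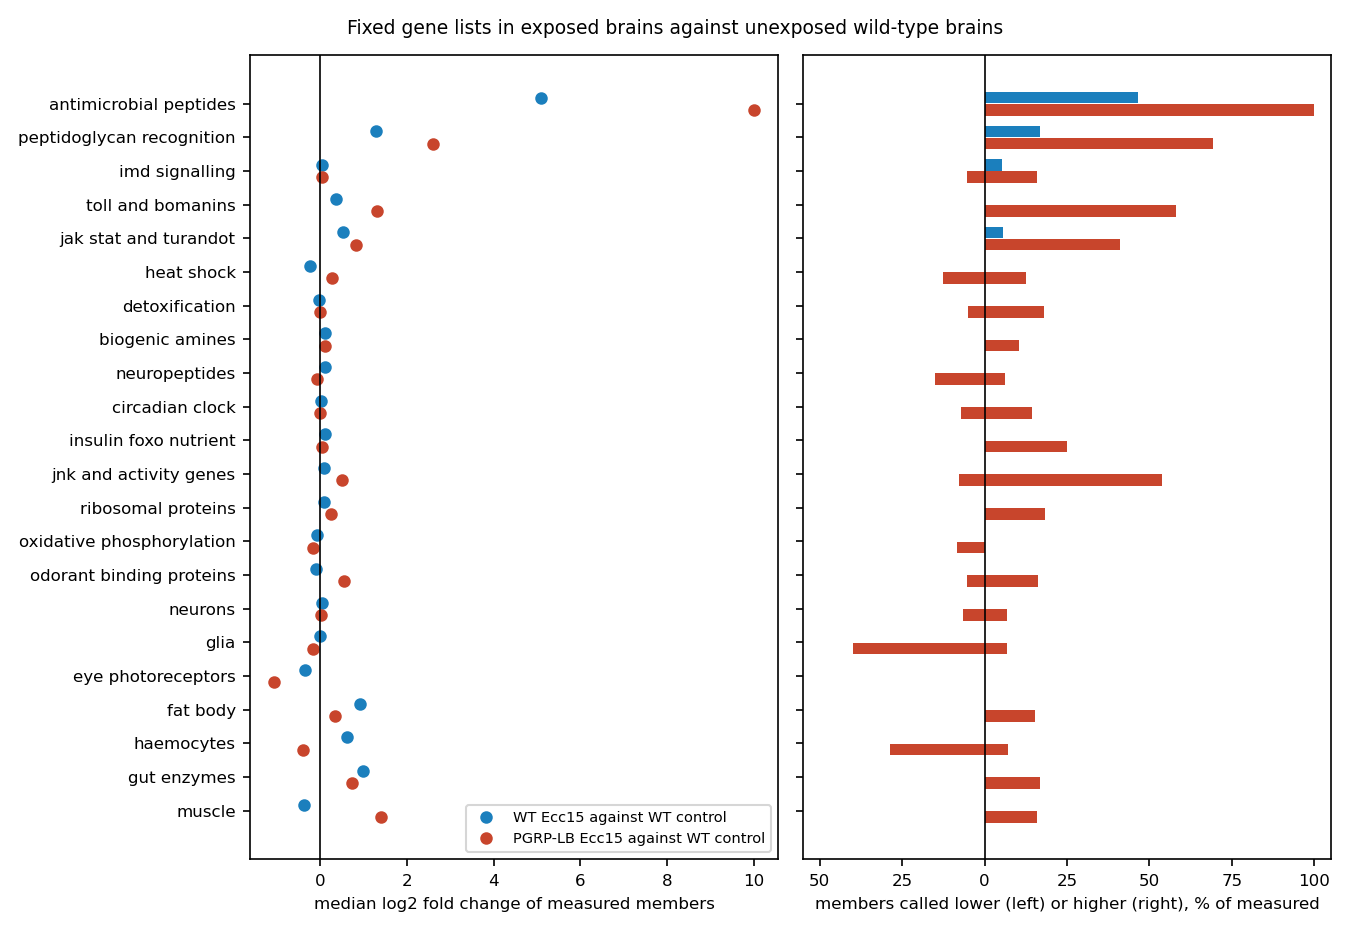
Median log2 fold change of the measured members of 22 gene lists (left) and the percent of members called higher or lower by limma (right, bars from 0), for WT Ecc15 in blue and PGRP-LB Ecc15 in red, both against WT control. The antimicrobial peptide list has medians of 5.08 and 10.01, and the haemocyte list medians of 0.61 and -0.39.

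Genes of neural function held calls in both directions, beside 1292 higher and 838 lower calls among all 13384 genes tested. The shares of biogenic amine genes called higher and of neuron markers called were not far from those over all genes. Of 29 biogenic amine genes 3 rose (2 adjusted over the list alone), which were the dopamine and serotonin synthesis enzyme Ddc (1.78-fold), ebony (1.66-fold) and Pu (log2 change 1.38). The list was not called (adjusted p = 0.0822). Tdc2, Tbh and Oamb had log2 changes of -0.10 (SE 0.11), 0.06 (SE 0.07) and 0.06 (SE 0.07) and were not called. Of 33 neuropeptide genes 2 rose and 5 fell (the same numbers adjusted over the list alone), with SIFa at 461 ± 91.1 against 1082 ± 114, Dh31 at 3904 ± 219 against 5436 ± 502 and Tk at 4759 ± 215 against 3426 ± 207 normalized counts. That list was not called (adjusted p = 0.0876). Of 15 neuron markers VAChT, the vesicular acetylcholine transporter, fell (7371 ± 211 against 11769 ± 335) and VGlut rose (12960 ± 684 against 10951 ± 355), with 1 and 1 adjusted over the list alone and no list call (adjusted p = 0.482, median 0.00 and mean -0.04, with a median of -0.09 after quantile normalization). Of 15 glial markers 6 fell and 1 rose (6 and 1 adjusted over the list alone), with Mdr65, a transporter of the blood-brain barrier, at 2171 ± 421 against 5502 ± 652 and the cortex glia gene wrapper at 2391 ± 308 against 4759 ± 299. The glial list was called lower (adjusted p = 0.00162, and adjusted p = 0.530 with an estimated correlation). Of 14 clock genes per (log2 change 0.77) and cwo rose and cry fell (3 higher and 1 lower adjusted over the list alone). The clock list was not called by camera (adjusted p = 0.858, median -0.02 and mean 0.04), while fry called it higher (adjusted p = 0.0252). The call of VGlut was lost without any 1 library, of Pu without any but PGRP-LB Ecc15 S3, of cwo without WT control S1 or S2 or any PGRP-LB Ecc15 library, of cry without WT control S1 or S2 or PGRP-LB Ecc15 S1 or S3, and of ebony without PGRP-LB Ecc15 S2 or S3.

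Lists of metabolism and stress held calls too, again beside 1292 higher and 838 lower calls among all 13384 genes tested. Of 20 insulin and nutrient genes 5 rose (5 adjusted over the list alone), among them the lipase bmm (1.98-fold) and Pepck2 (13.3-fold), with no list call (adjusted p = 0.255). The log2 change of Pepck2 was 3.73, against 4.38 without PGRP-LB Ecc15 S1 and 3.04 without PGRP-LB Ecc15 S2. Of 87 ribosomal protein genes 16 rose (20 higher and 1 lower adjusted over the list alone), with RpLP0 up 2.22-fold and a list median of 0.24. Of 71 nuclear oxidative phosphorylation genes 6 fell (3 adjusted over the list alone), with a median of -0.17. Camera called the ribosomal list higher and the oxidative phosphorylation list lower (adjusted p = 9.83e-09 and 3.29e-05, each with adjusted p = 0.659 with an estimated correlation). Both calls were also lost with fry (adjusted p = 0.113 and 0.176). Of 39 detoxification genes 7 rose and 2 fell (10 and 3 adjusted over the list alone), and of 16 heat shock genes 2 rose and 2 fell (3 and 3 adjusted over the list alone), with no list call (adjusted p = 0.323 and 0.829). The heat shock median of 0.28 turned to -0.03 after quantile normalization. Of 37 odorant-binding protein genes 6 rose and 2 fell (8 and 2 adjusted over the list alone; adjusted p = 0.0495, and adjusted p = 0.659 with an estimated correlation), with Obp56g at 1122 ± 555 against 4.33 ± 3.51.

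Markers of other tissues also differed. Of 14 haemocyte markers 4 fell and 1 rose (5 and 2 adjusted over the list alone), with the prophenoloxidase genes PPO1 at 319 ± 209 against 1593 ± 188 and PPO2 at 632 ± 86.1 against 2170 ± 89.4. Of 19 muscle genes 3 rose (4 adjusted over the list alone), which were Mlp84B (4.33-fold), Act79B and sls (4.10-fold). Of 24 gut enzymes 4 rose (4 adjusted over the list alone), among them the amylases Amy-p (89.7-fold) and Amy-d (20.8-fold). Of 13 fat body markers mag and Obp99b rose (2 adjusted over the list alone), and of 19 photoreceptor genes limma called none, over all genes or adjusted over the list alone, while the authors' deposited table has norpA lower (adjusted p = 0.0169). The haemocyte, muscle, gut and photoreceptor lists were called at adjusted p = 0.0495, 0.00364, 0.0296 and 0.0296, each with adjusted p = 0.659 with an estimated correlation, and the fat body list was not (adjusted p = 0.255). Libraries of one group differed in these tissues, with the photoreceptor opsin ninaE at 122196, 145111 and 14405 in WT control and at 70448, 50473 and 7743 in PGRP-LB Ecc15, on the common scale of all 9 libraries. The calls of sls and Mlp84B were lost without WT control S1, those of sls, Mlp84B and Act79B without any 1 PGRP-LB Ecc15 library, that of PPO1 without PGRP-LB Ecc15 S3, and that of Obp99b without WT control S1 or S3 or any PGRP-LB Ecc15 library (adjusted p up to 0.209, without both WT control S3 and PGRP-LB Ecc15 S2). The list calls were lost for photoreceptors without WT control S1 or S2 or PGRP-LB Ecc15 S3, for haemocytes without WT control S1 or S2 or PGRP-LB Ecc15 S1, for gut enzymes without WT control S2, and for odorant-binding proteins without WT control S2 or S3 or PGRP-LB Ecc15 S1 or S2. With fry the haemocyte, muscle, photoreceptor and odorant-binding lists lost their calls (adjusted p = 0.177, 0.234, 0.366 and 0.234). Over all 10 alternatives the photoreceptor, haemocyte and odorant-binding calls were lost in 6, 6 and 7.

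**Figure D3:**
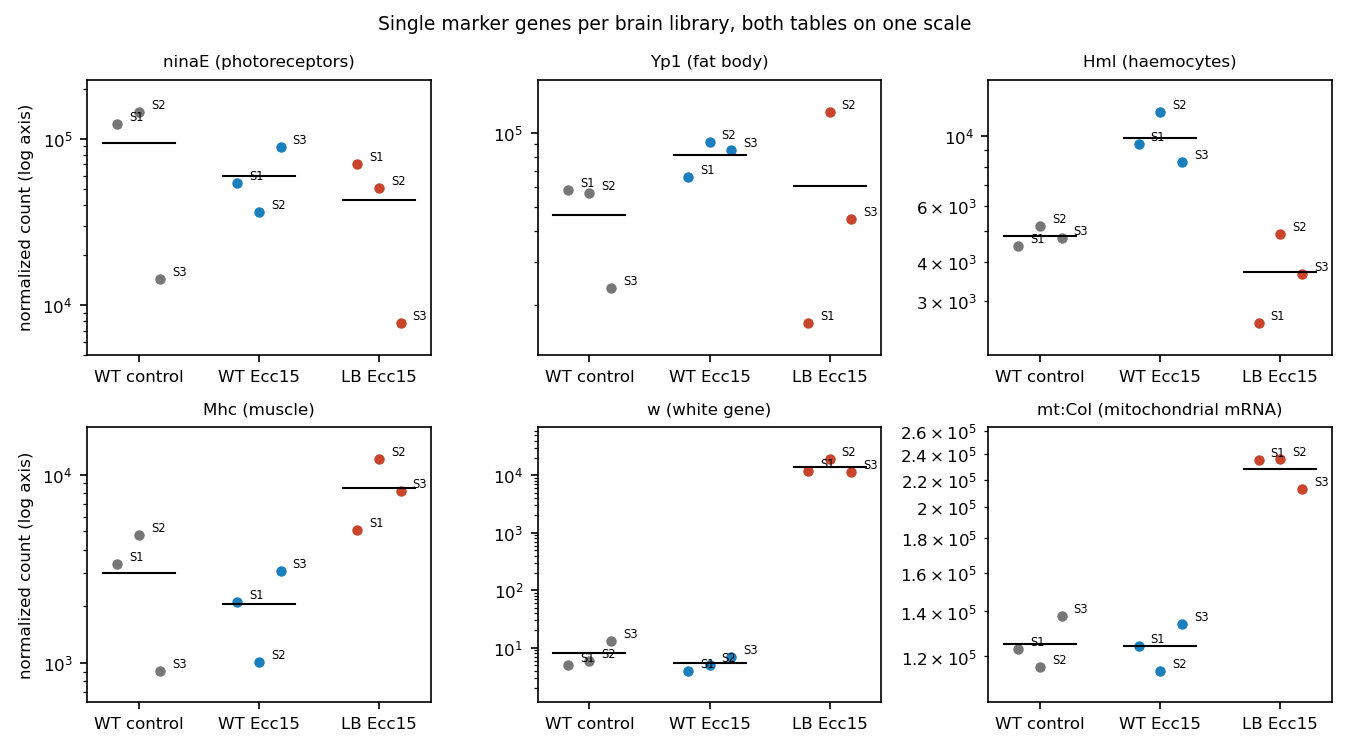
Normalized counts on a log axis of 6 single genes in each of the 9 brain libraries, with both tables put on one scale by factors of 0.985 to 1.01; points are libraries S1 to S3 of WT control (grey), WT Ecc15 (blue) and PGRP-LB Ecc15 (red), and lines are means. The w gene lies between 4 and 13 in the wild-type libraries and between 11274 and 19205 in the mutant ones, and ninaE is lowest in WT control S3 (14405) and PGRP-LB Ecc15 S3 (7743).

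How many genes were called in the second comparison depended on the number of libraries and the scaling. Without PGRP-LB Ecc15 library S1, S2 or S3 in turn, 776, 742 and 787 genes were higher and 422, 430 and 416 lower. Of these, 740, 726 and 748 of the higher and 408, 403 and 409 of the lower genes were also called with all libraries. Without WT control library S2, 387 were lower. Without both WT control S3 and PGRP-LB Ecc15 S2, 418 were higher and 210 lower. After quantile normalization, which moved the median log2 change of all genes by -0.10, 1054 were higher and 1298 lower, so that 44.8% of the calls were higher in place of 60.7%. Of these genes, 1030 of the higher and 829 of the lower were also called without it.

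How exposed mutant brains differ from exposed wild-type brains is asked by setting PGRP-LB Ecc15 against WT Ecc15. Without unexposed mutant libraries, an altered response cannot be told apart from a difference of genotype or strain present before exposure. No table holds both groups and the tables were scaled separately, so the values stand side by side against the same WT control libraries, without a test. DptA had a log2 change of 11.43 (SE 0.31) in the mutant and 5.91 (SE 0.45) in the wild type. AttD had 11.76 (SE 0.55) and 5.26 (SE 0.74), AttA 8.70 (SE 0.39) and 2.57 (SE 0.73), and pirk 4.56 (SE 0.29) and 1.46 (SE 0.35). In the wild type AttA had 3.41 and AttD 5.84 without WT Ecc15 S3, and without WT control S3 AttD had 12.47 in the mutant and 5.96 in the wild type, there with a call (limma adjusted p = 0.0497). Rel had 2.96 (SE 0.12) and 0.73 (SE 0.07), and Mtk, which was chosen for this pair after its values were seen, had 7.74 and 5.45 (SE 0.37). The 3 octopamine genes Tdc2, Tbh and Oamb were called in neither.

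Of the 12851 genes tested in both comparisons, limma called 15 higher in both and 0 lower in both, and the authors' deposited table has 80 higher and 11 lower in both. Independent lists of these sizes (16 and 1189 genes higher) would share 1.48. In 100 simulations of unchanged groups sharing the controls, the overlap was 0 in each. With no gene changed hardly any call can arise, so these simulations do not give the overlap expected when many genes change. The log2 changes correlated across genes with r = 0.487, where the simulated value was 0.501, and genes are not independent replicates. Their covariance was 0.254 against a simulated 0.0764, a difference of 0.178. With all 9 libraries on one scale, a setting chosen after seeing the data, the overlap was 26 in place of 15. The 3 controls cannot be split into parts of at least 2, so part of the overlap may come from the shared controls. The gene called by limma in the wild type alone was CG42711, at 458 ± 69.2 against 133 ± 13.1 in the wild-type table, and at 73.3 ± 21.2 against 130 ± 12.7 in the PGRP-LB table (limma adjusted p = 0.0565, and 0.0358 in the authors' deposited table).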

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

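The joint fit of all 9 libraries, and every test of an explanation for the antimicrobial peptide pattern, was chosen after the result was seen. Results stand here because the effect of exposure plus genotype, against the same controls, differed between PGRP-LB Ecc15 and WT Ecc15 by the joint limma test of the difference itself. Differences are PGRP-LB Ecc15 minus WT Ecc15 on the log2 scale.

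The 13 genes listed next, of immune function or named in the comparisons above, were higher in each PGRP-LB Ecc15 library than in each WT Ecc15 library. The differences were 6.542 for AttD (adjusted p = 0.000162), 6.13 for AttA (0.000303), 5.64 for CecA1 (0.000107), 5.51 for DptA (7.37e-05), 5.498 for CG45045 (0.000122), 5.16 for Dro (5.53e-05) and 4.97 for CecB (0.000219). Smaller ones were 4.11 for DptB (0.000640), 3.39 for CecC (0.000230), 3.11 for pirk (0.000269), 2.93 for PGRP-SB1 (0.00267), 2.30 for Mtk (0.00711) and 1.73 for PGRP-LB (0.00210). Without WT Ecc15 S3 the difference was 5.28 for AttA and 5.96 for AttD. Of the antimicrobial peptide genes, 15 of 15 were called higher.

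Among gene lists, the camera test called 11 differences. The medians were 5.16 for antimicrobial peptides (adjusted p = 1.64e-16), 2.50 for peptidoglycan recognition (3.11e-07), 0.97 for Toll and Bomanins (3.71e-08), 0.0889 for JAK-STAT and Turandot (0.0168), 0.46 for JNK and activity genes (0.00624), 0.16 for ribosomal proteins (1.54e-05) and 1.79 for muscle (4.28e-05). Negative medians were -0.93 for haemocytes (5.96e-05), -0.30 for neuropeptides (0.000774), -0.15 for glia (0.000434) and -0.0606 for oxidative phosphorylation (0.0139). No list was called with an estimated correlation, where adjusted p was 0.321 to 0.772 for these 11. With fry 8 lists were called, among them antimicrobial peptides (adjusted p = 0.000783) and, not called by camera, Imd signalling (0.0107). Oxidative phosphorylation also lost its call with fry (adjusted p = 0.4), with quantile normalization, and without WT Ecc15 S2 or S3 or PGRP-LB Ecc15 S1. JAK-STAT lost it without WT Ecc15 S3 or PGRP-LB Ecc15 S2 (up to 0.0763), and muscle, neuropeptides and ribosomal proteins with fry (0.0674, 0.0645 and 0.154).

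The higher antimicrobial peptide genes of the mutant libraries were weighed against tissue carried along with the brains. The prediction was that more fat body tissue would raise its markers by at least as much. This holds only where little marker RNA comes from the brain itself, which was not measured. In control brains 9 of 14 fat body and 13 of 14 haemocyte markers had a mean of at least 100, against 2 of 15 peptide genes. The median difference of the fat body markers was -0.472 (95% bootstrap interval over members -0.832 to 0.0399), against 5.16 (4.56 to 5.76) for the peptide genes. The same was predicted for more haemocytes, and their markers had a median of -0.926 (interval -1.67 to -0.351). Against WT control the fat body median was 0.33 in PGRP-LB Ecc15 and 0.91 in WT Ecc15, and the haemocyte median -0.39 and 0.61. The negative differences thus hold a rise of these markers in WT Ecc15. Whether exposure changes the markers within the tissue was not tested. The intervals cover spread over genes that change together, not spread over libraries. Per library, the mean log2(value + 1) of fat body markers was 9.995 to 10.47 in WT Ecc15 and 9.209 to 11.185 in PGRP-LB Ecc15. That of haemocyte markers was 10.865 to 11.281 and 9.653 to 10.589, and that of peptide genes 7.741 to 9.502 and 13.794 to 14.727. PGRP-LB Ecc15 S2 was highest for both fat body markers and peptide genes. In control brains 12 of 14 fat body and all 14 haemocyte markers had a mean of at least 5, and 1 fat body marker (Obp99b) is in another list too. The abundant fat body gene Yp1 lay at 66356 to 91275 in WT Ecc15 and at 16899 to 121427 in PGRP-LB Ecc15, and Hml at 8262 to 11926 and 2554 to 4885. A stronger response of the same amount of carried-over tissue may remain, as markers of amount do not test it, and 0 unexposed mutant libraries were there to separate the genotype alone from the response to exposure.

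With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split of WT Ecc15 and WT control called 16 genes, and the highest of the other splits 14, with 1 split at least as large as the real one, the real one itself. For PGRP-LB Ecc15 and WT control the real split called 2130 genes and the highest other 0 (1 split as large), and for PGRP-LB Ecc15 and WT Ecc15 2199 against 1 (1 split as large). For gene lists, the real splits called 14, 13 and 11 in these 3 comparisons and the highest other splits 10, 15 and 13, with 1, 3 and 5 of the 10 splits calling at least as many.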

How the results depend on the processing

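The joint scale, the ninaE covariate and the set of doubted libraries were chosen after seeing the data. No direction of a named gene or list reversed while it was called. For WT Ecc15 against WT control, genes higher numbered 16, against 28 on the joint scale and 29 with ninaE as a covariate, and 0 to 19 with one library left out (0 genes lower throughout). For PGRP-LB Ecc15 against WT control, genes higher numbered 1292 (742 to 1059 with one library left out, and 418 without both WT control S3 and PGRP-LB Ecc15 S2), and genes lower 838 (1298 after quantile normalization, 1285 on the joint scale, 387 to 673 with one library left out, 210 without both). For PGRP-LB Ecc15 against WT Ecc15, genes higher numbered 1319 (813 to 1010 with one library left out) and genes lower 880 (1393 after quantile normalization, 568 with the fold threshold, 536 to 674 with one library left out). List calls numbered 14, 13 and 11. They fell to 0, 0 and 0 with an estimated correlation, and in the wild type to 2 with fry. The overlap of calls was 15, and 26 on the joint scale. Fewer libraries leave less power; the cause of the other shifts was not tested. All other counts stayed within 1.5 times. For single named genes, pairs of gene and alternative that lost the call numbered 59 (197 kept it or stayed uncalled, 3 gained it), 132 (1206) and 57 (1215) in the 3 comparisons, and for lists 42, 33 and 21 lost and 4, 8 and 9 gained. The planned DESeq2 and edgeR alternatives were not run, because the deposited values are not counts. No paired analysis was possible because the columns carry no replicate numbers and the titles of 2 groups share at most 1. At the estimated depth of 19.4 M (mega) reads in the shallowest library, genes with values of a few counts, such as CecB or Gr59d, have imprecise folds.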

Other observations

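The joint fit, the list of mitochondrial mRNAs and the tests on it, and the look at w beside ninaE, were chosen after the result was seen. In the joint fit 1319 genes were higher and 880 lower in PGRP-LB Ecc15 than in WT Ecc15 brains among 13224 tested (limma). Among the largest differences were edin (log2 difference 10.52, SE 0.47), IBIN, an infection-induced peptide gene (7.50, SE 0.64, and 8.14 without WT Ecc15 S1), CG13492 (9.61, SE 0.53), CG42697 (8.26, SE 0.35; it overlaps GEFmeso on the same strand) and zuc (6.98, SE 0.57). Among the lowest were Oatp33Ea (-6.94, SE 0.41), CG9377 (-5.58, SE 0.51) and Cyp28a5 (-4.85, SE 0.11). Without WT Ecc15 S2, 813 genes were higher and 536 lower, and without WT Ecc15 S1 570 were lower. After quantile normalization 1078 were higher and 1393 lower, 43.6% of the calls higher in place of 59.98%. Of 33 neuropeptide genes 7 were lower and 2 higher, among them SIFa (-0.98, SE 0.16), Dh31 (-0.57, SE 0.07) and ITP (-0.55, SE 0.07), with Tk higher (0.47, SE 0.06). Tdc2, Tbh and Oamb differed by -0.13 (SE 0.10), -0.06 (SE 0.06) and -0.03 (SE 0.06), none called.

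On the common scale the haemocyte gene Hml stood at 4497, 5183 and 4754 in WT control, at 9398, 11926 and 8262 in WT Ecc15 and at 2554, 4885 and 3664 in PGRP-LB Ecc15 libraries. In the joint fit 7 of 14 haemocyte markers were lower in the mutant, among them PPO1 (-3.04, SE 0.42), PPO2 (-2.08, SE 0.17) and Hml (-1.45, SE 0.21). Against WT control limma called 0 of the 14 in WT Ecc15, where all 14 lay above 0 (median 0.61, 6 higher adjusted over the list alone). In PGRP-LB Ecc15 it called 4 lower and 1 higher (median -0.39, 5 and 2 adjusted over the list alone). Hml had log2 changes against WT control of 1.02 (SE 0.13) in WT Ecc15 and -0.43 (SE 0.21) in PGRP-LB Ecc15. Its joint difference thus holds a higher value in WT Ecc15 as well. Of 19 muscle genes 10 were higher in the joint fit, among them sls (2.61, SE 0.55), with Mhc at 5096 to 12124 in mutant and 911 to 4813 in wild-type libraries. With an estimated correlation neither list difference was called (adjusted p = 0.476 and 0.575). Of the lists not called by camera, 19 Imd genes had 3 higher and 1 lower, 39 detoxification genes 10 and 2, 16 heat shock genes 4 and 2, 29 biogenic amine genes 3 and 2, 20 insulin genes 6 and 0, 14 clock genes 1 and 1, 37 odorant-binding proteins 3 and 0, 25 gut enzymes 4 and 0, 13 fat body markers 1 and 0, 15 neuron markers 0 and 1, and 19 photoreceptor genes 0 and 0. Among these lists fry called only the Imd list, as higher (adjusted p = 0.0107). PGRP-LB Ecc15 library S2 stood apart with a ribosomal RNA pseudogene, 28SrRNA-Psi:CR40596, at 1694, against 2 to 190 in the other 8 libraries.

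The w gene was at 11274 to 19205 in the mutant and 4 to 13 in all wild-type libraries, and ninaE was at 145111 in the wild-type library with w at 6 and at 7743 in the mutant library with w at 11274. Of 217 genes differing more than 8-fold between the exposed groups, 178 were higher in the mutant and 39 lower, and 31 belong to a fixed list. Whether these lie on a chromosome stretch carried along with the mutation was predicted before the test. Of the 212 with a location, 0% lay within 1 Mb of PGRP-LB (95% exact binomial interval 0 to 1.73%), so a stretch of that width was not their source. The window held only 248 tested genes and could hardly have held most of the 212. A wider linked stretch was not tested, and 45 of these genes lay on the rest of 3R. Of 248 tested genes in that window 16.5% were called, against 16.9% of the other 2833 on 3R (Fisher's exact test, two-sided, p = 0.930). The w gene, on chromosome X, was low in exposed and unexposed wild-type libraries alike, so exposure did not raise it in the wild type. Whether exposure changes it in the mutant cannot be seen here. A total over the gene also does not show from which place in the genome its RNA came. Differences of the strains elsewhere in the genome may account for part of the other genes, which was not tested. No library of the mutant strain without exposure was analysed here.

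Of 13 mitochondrially encoded mRNAs, 7 were called higher and 0 lower in the mutant brains in the joint fit, with a median log2 difference of 0.656, and mt:CoI stood at 213001 to 236065 in mutant and 114298 to 137666 in wild-type libraries. Against WT control, limma called 8 higher and 0 lower in PGRP-LB Ecc15 and the authors' deposited table has 8 and 1 (mt:ND6, limma log2 change -0.69, SE 0.22, and -0.43, SE 0.20, in the joint fit), and in WT Ecc15 both called 0 (limma median -0.05). Of 19 muscle genes 10 were called higher (median 1.79), but more tissue rich in mitochondria, such as muscle, would raise the nuclear oxidative phosphorylation genes too. Their median difference was -0.0606 (bootstrap interval over members -0.0899 to -0.0401, which leaves out spread over libraries). Limma called 0 of these 71 genes higher and 4 lower, and fry did not call the list (adjusted p = 0.4). These values argue against such tissue as the main source. Capture or leakage acting alike on all mitochondrial RNA would raise the ribosomal RNAs as much as the mRNAs. In the joint fit mt:lrRNA differed by 0.226 (SE 0.152, 95% interval up to 0.568) and mt:srRNA by 1.12 (SE 0.35). Against WT control, where the mRNA median was 0.71, they differed by -0.03 (up to 0.370) and 0.19 (SE 0.39). In the joint fit these RNAs lay on either side of the mRNA median, so the values do not decide on such capture or leakage. Capture that favours mRNAs, and a different mitochondrial genome in the mutant strain, were not tested, as 0 read files were analysed.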
